A study of Caenorhabditis elegans with 13 samples.

How the data were processed

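Embryo RNA of 8 groups and Hi-C contact maps of N2 and dpy-21(y607) embryos were analysed. The 3 H4K20me1 ChIP samples were not analysed here. Per the labels' protocols, RNA came from mixed-stage embryos of bleached adults, poly(A)+ RNA was selected and fragmented, cDNA was primed at random, and libraries followed a TruSeq protocol that the labels do not call strand-specific. Values of genes that overlap a neighbour or have near-identical copies are therefore uncertain. Mutant strains and N2 were grown on HB101 bacteria, and N2-L4440 and set-1(RNAi) on HT115 bacteria over 2 generations, per the labels. Per the labels there were 2 populations for N2-L4440 and 3 for set-1(RNAi). The labels gave no number of libraries for the other groups.

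Per the submitters' processing notes, RNA reads passed through CASAVA 1.8, cutadapt 0.9.5, GSNAP, HTSeq 0.5.4p3 and DESeq, whose version and settings were not given. The genome build and annotation of the RNA analysis were not given in the sources used here. The expression signal was deposited as the authors' mean over a group's libraries of normalized reads, per the file headers, with 1 value per gene and group. The fold was deposited by the authors and equals the ratio of the mutant mean to the control mean. The p-value used was the authors' deposited adjusted p, whose adjustment method was not stated. Unadjusted p-values and values per library were not analysed here. Hi-C maps were made by DpnII digestion in nuclei, per the labels, and placed on ce11, per the submitters' processing notes. The contact signal was deposited by the authors as a balanced map in bins of 50 kb with a total of 1000000, 2008 bins in all, of which 22 were empty in N2 and 24 in y607. The authors averaged 3 maps into N2 and 2 into y607 and scored them with cworld 0.41.1, per the file headers. The authors' deposited insulation was on a log2 scale, and their deposited z-score of contact over the expectation at each distance was used only as an alternative.

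The deposited tables listed 20081 sequence names, with 9 repeated lines of 3 names in them, and no column of values was left unmapped. For medians, genes with a mean over the 8 groups of at least 10 were kept, log2 ratios were taken after adding 1, and the median of autosomal genes was subtracted from that of X-linked genes to give the X shift. Intervals are 95% ranges of 1000 bootstrap draws over genes, so they describe genes and not embryos. Each X-linked median, without subtracting autosomes, and each list median was set against 10000 random lists of as many genes drawn from 10 bins of expression with a seed of 1. Those percentiles describe a list's place among genes and test nothing between groups. The 11 gene lists covered the dosage compensation complex, condensin and cohesin, sex determination, histone methylation, heat shock, apoptosis, the cell cycle, cuticle, HOX, RNAi machinery and pathogen response. The 8 marker lists covered intestine, epidermis, body muscle, pharynx, neurons, germline and early maternal RNA, the adult body, and sperm. Both kinds were fixed before the data were examined, and 279 of their 282 symbols were matched. Of 114 list medians, 47 lay outside the central range of random lists. Independent genes would put 5.7 there. Genes of a list can vary together and most comparisons share N2, so the excess is no test.

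Named genes followed a rule fixed before the data were examined. In e428 and y607 it took, among genes past the threshold, the 8 X-linked and 4 autosomal genes with the largest rises and the 8 with the largest falls. In the other comparisons it took 4 rises and 4 falls, and it added dpy-21, set-1, set-4 and members of the fixed lists. Its part on single libraries could not be applied. Genes with means of at least 500, genes short of the threshold, hrg-7, lea-1, tatn-1, hrg-1, ugt-64 and the remaining set-4(n4600) calls were named after their values were seen.

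For Hi-C, boundaries were the 8 strongest local minima per chromosome of the deposited N2 insulation, and strength was the mean of the highest values within 250 kb on either side less the minimum. Contact by distance was each window's mean share of the contacts between different bins of the same chromosome. Insulation recomputed from the maps with a window of 500 kb had correlations with the deposited N2 profile from 0.79 on chromosome V to 0.999 on chromosome I, with 0.917 on X. Steps were tested on simulated data. For a simulated group against N2 with 14356 genes, an X shift of 0.1 put in came back as 0.0845, and -0.0064 was found with none put in, while 6 of 6 planted boundaries were found.

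The design planned a test across libraries, gene set tests and permutations. With 1 value per group none of these could be run, so the authors' calls over all genes in their tables took their place, and adjustment over a list alone was not possible. N2 served as control for 5 comparisons, so part of any overlap among them can come from N2, and N2-L4440 was added as a separate untreated group after the values were seen. N2-L4440 differed from N2 in food and in an all-gene median of 0.29, so only values less autosomes or less all genes were compared across them. Alternatives covered the filter, pseudocount, scaling, summary, matching on expression, threshold, control group, boundary definition and reference total. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.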

Results

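Caenorhabditis elegans hermaphrodites lower expression from their X chromosomes through the dosage compensation complex, a condensin-based assembly. DPY-21 belongs to that complex and demethylates H4K20me2 to H4K20me1, SET-1 places H4K20me1, and SET-4 places the higher methylation states. The series addresses how this demethylase shapes X conformation and X repression. Poly(A)+ RNA of mixed-stage embryos was compared between N2 and 5 mutant groups, dpy-21(e428), dpy-21(y607), dpy-21(y618), dpy-21(y622) and set-4(n4600), and between set-1(RNAi) and the vector control N2-L4440. In situ Hi-C compared N2 with dpy-21(y607). The labels gave no molecular description of the dpy-21 alleles.

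Expression came as 1 pooled value per gene and group, the authors' mean normalized read count, with the authors' fold and adjusted p for each comparison. No replicate check was possible on such values, so calls below are those of the authors' DESeq at an adjusted p under 0.05. Medians of X-linked genes, autosomal genes and gene lists are descriptions without a test. The authors' means summed to 26.7 M normalized reads in N2, 30.8 M in N2-L4440, 25.2 M in set-1(RNAi), 25.8 M in set-4(n4600), 25.7 M in e428, 27.4 M in y607, 27.1 M in y618 and 25.0 M in y622. The smallest steps between low values required at least 5 libraries for N2, 7 for e428, 2 for N2-L4440 and 3 for every other group. Numbers of calls are therefore not comparable between alleles. The medians covered 15536 genes with a mean of at least 10, of which 2331 were X-linked and 13205 autosomal.

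The RNA of the targeted genes matched the names of the set-4(n4600) and set-1(RNAi) groups. As the authors' deposited table gives it, set-4, the H4K20 di- and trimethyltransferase gene, had a mean of 4.28 in set-4(n4600) against 1780.4 in N2 (fold 0.0024, adjusted p 3.45e-237). The authors' deposited table gave set-1, the monomethyltransferase gene, a mean of 2176 in set-1(RNAi) against 7368 in N2-L4440 (fold 0.295, adjusted p 1.42e-67). The authors' deposited table gave dpy-21 itself a mean of 13939.8 in N2 and 8118 in e428 (fold 0.582, adjusted p 8.45e-07). In y607, y618 and y622 the authors' deposited table gave dpy-21 means of 13467, 13482 and 11553.5, with folds of 0.966, 0.967 and 0.829, none past the test, so its RNA level does not check those 3 group names. The authors' deposited table also placed dpy-21 at 0.593 of its control in set-1(RNAi) (adjusted p 1.95e-15), where its mean was 22315 in N2-L4440 and 13222 after knockdown. The knockdown mean cannot be set directly against the N2, y607 and y618 means, because N2-L4440 lay 0.29 log2 above N2 over all genes. How much of the fall in set-1(RNAi) came with a high control mean is therefore not known. Since dpy-21 RNA also fell where dpy-21 was not targeted, its fall does not check the e428 name.

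The comparison of dpy-21(e428) with N2 asked which genes differ in expression in this allele. X-linked genes dominated the answer. The calcium-store protein calsequestrin (csq-1) and the muscle troponin T tnt-2 rose from X, as did the antibacterial-factor-related gene abf-6 and the transthyretin-related genes ttr-38 and ttr-30. Among X-linked tissue markers the pharyngeal myosin gene myo-2, the troponin I gene unc-27, the synaptogyrin gene sng-1, the apical junction gene ajm-1 and the nuclear receptor gene nhr-25 rose, while elt-2, cpr-6, elt-3, dpy-7, hnd-1 and peb-1 did not pass the test. By the authors' deposited table, 1201 genes were higher and 298 lower, and 952 of the higher genes were X-linked. X thus supplied 79.3% of the rises while it held 2792 of 19995 listed genes, and 34.1% of X-linked genes were called higher against 1.45% of autosomal genes. The folds were modest, with a median of 1.50 among the 952 genes, a lowest decile at 1.30 and a highest decile at 1.99 in the authors' deposited table. Only tatn-1 and hrg-1 were lower on X, a count of 2, while 296 autosomal genes were lower.

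The largest X-linked rises in the authors' deposited table were ttr-38 (fold 5.68, adjusted p 0.0341), abhd-3.2 (4.62, 1.79e-08), ttr-30 (4.49, 6.41e-10), C45B2.2 (4.42, 3.51e-10) and F46F2.3 (4.38, 0.00484). Next in the authors' deposited table came abf-6 (fold 4.17, adjusted p 0.000202), the sulfatase gene sul-3 (3.98, 5.46e-06) and C02F12.5 (3.90, 0.000329). Several of these rises began near the floor, with N2 means of 2.33 for ttr-38, 4.61 for F46F2.3, 7.33 for abf-6 and 8.55 for C02F12.5. The rest had N2 means from 11.6 to 77.8. Among X-linked genes with means of at least 500, the authors' deposited table gave csq-1 a rise from 2264 to 5038 (fold 2.22, adjusted p 4.26e-09), tnt-2 a fold of 2.24 (2.71e-07) and B0403.5 a fold of 2.18 (2.42e-06). The 249 autosomal rises had a median fold of 2.16 in the authors' deposited table and were led by the ground-like gene grl-21 (fold 10.9, adjusted p 4.5e-13), F56H6.7 (10.7, 0.00742), the acyltransferase gene oac-43 (9.47, 1.34e-06) and F56A4.3 (8.88, 0.00351). Their N2 means were 49.6 for grl-21 but only 3.19 for F56H6.7, 2.75 for oac-43 and 1.37 for F56A4.3. Falls in the authors' deposited table included the alcohol dehydrogenase gene sodh-1 (fold 0.317, adjusted p 3.37e-05), the tyrosine aminotransferase gene tatn-1 (0.474, 6.9e-07), Y48G8AL.12 (0.132, 1.98e-14), K12H6.5 (0.148, 0.0369) and C17F4.3 (0.219, 2.16e-08). K12H6.5 fell from an N2 mean of only 4.04. The deepest falls sat side by side on chromosome V. These were C25F9.14 (fold 0.00226, adjusted p 1.47e-63), C25F9.11 (0.00289, 1.34e-38), the chemoreceptor gene srw-85 (0.0036, 3.83e-82), M04C3.1 (0.00646, 1.1e-100) and C25F9.2 (0.129, 2.09e-05) in the authors' deposited table.

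Across all expressed genes of e428 the X median was 0.38 log2 and the autosomal median -0.05, an X shift of 0.43 log2 (95% bootstrap interval over genes 0.41 to 0.45), equal to 1.35-fold. Of X-linked genes 89.3% lay above N2, against 41.5% of autosomal genes. No single autosome moved beyond -0.02 to 0.03 from the rest, and the X median lay above all 10000 random gene lists matched for expression. The shift was 0.35 among genes with means over the 8 groups of 10 to 100, 0.47 from 100 to 500, 0.43 from 500 to 3000 and 0.42 above that. With N2-L4440 as the untreated group the e428 shift was 0.54.

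Gene lists in e428 had medians near 0 apart from cuticle, stress, intestine and adult carried-over genes, the last of which are given below. The cuticle collagen list, whose products form the larval and adult exoskeleton, had a median of -0.49 log2, below all 10000 matched random lists. Of its genes 5 were lower, dpy-9 (0.377), dpy-10 (0.775), dpy-14 (0.77), dpy-17 (0.725) and sqt-3 (0.728), and 1 was higher, lon-3 (2.00), in the authors' deposited table. The pathogen and stress-response list had a median of 0.30 (percentile 99.7). The authors' deposited table called 6 of its genes higher, dod-24 (2.83), dod-22 (2.29), cdr-1 (2.17), mtl-2 (2.06), the superoxide dismutase gene sod-3 (2.04) and dod-17 (1.55). That list did not keep its place against N2-L4440, where its median less that of all genes was -0.12. Intestine markers had a median of 0.20 against N2 and 0.08 less all genes against N2-L4440. X-linked list members that rose in the authors' deposited table were sod-3, myo-2 (1.71), unc-27 (1.56), the H3K27 demethylase gene jmjd-3.1 (1.48), sng-1 (1.45), ajm-1 (1.41), nhr-25 (1.27) and hsp-43 (1.24). The dosage compensation complex list had a median of -0.00, with dpy-21 its only call, and the heat shock list one of -0.07, with the mitochondrial chaperone gene hsp-60 lower at 0.755 in the authors' deposited table. Cell cycle genes (-0.04), sex determination genes (0.04), condensin and cohesin genes (-0.03), apoptosis genes (-0.04) and HOX genes (0.00) held no call. Germline and early maternal genes had a median of 0.05 (percentile 97.6) and RNAi machinery genes 0.07 (92.3), both without a call, and medians were 0.07 for pharynx, 0.02 for body muscle, -0.04 for neuron and 0.01 for epidermis markers.

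**Figure D1:**
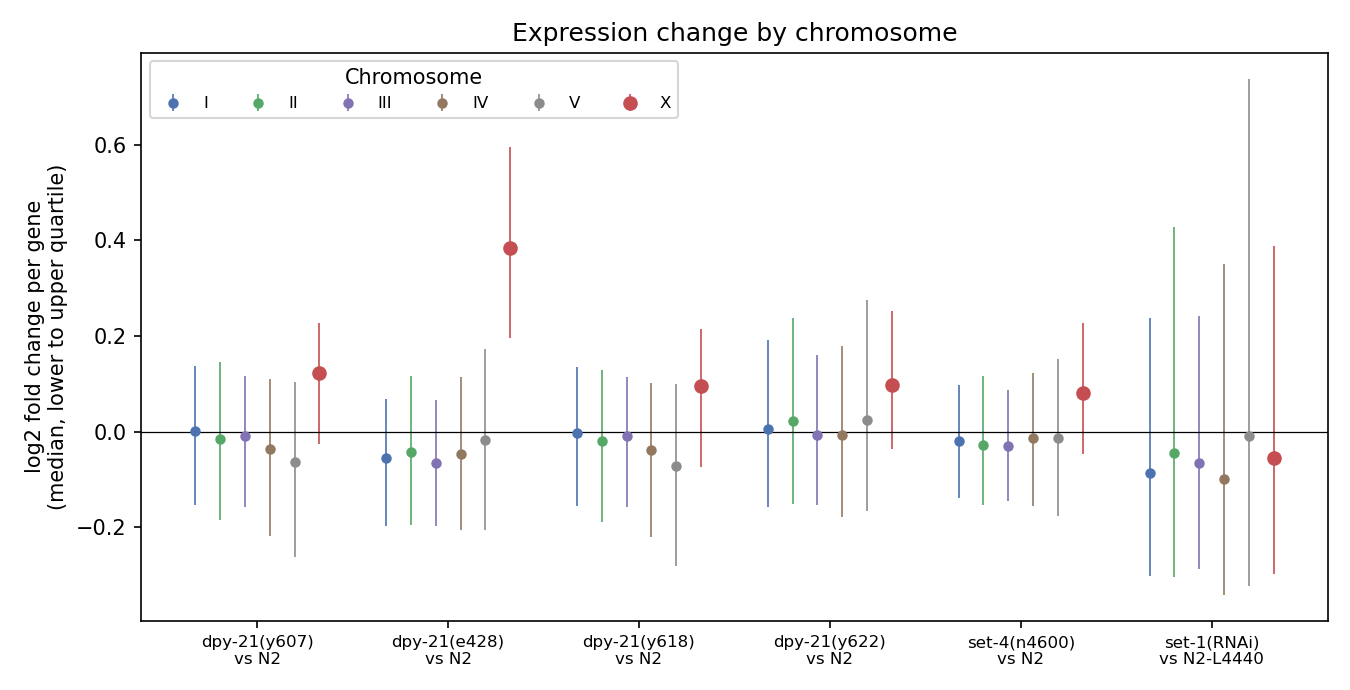
Median log2 ratio of each chromosome in 6 comparisons of embryo RNA, with lines from the lower to the upper quartile of genes. X stood apart in all 4 dpy-21 alleles and in set-4(n4600), with a shift of 0.43 in e428, and did not in set-1(RNAi).

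The y607, y618 and y622 comparisons asked whether X-linked expression also differs from N2 in these dpy-21 alleles. X-linked genes as a group lay slightly above autosomal genes in all 3. Single genes hardly passed the authors' test. The chemoreceptor gene srw-85 fell in y607 and the heme-response protease gene hrg-7 fell in y622. Early maternal and germline genes, including the P-granule gene pgl-3, had higher values in all 3 alleles, while pharynx, neuron and cuticle genes had lower ones. The P-granule gene meg-2, which is X-linked, also had higher values in all 3.

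The X shift was 0.15 log2 in y607 (interval 0.14 to 0.16), 0.12 in y618 (0.11 to 0.13) and 0.09 in y622 (0.08 to 0.10), equal to 1.11-fold, 1.09-fold and 1.06-fold. The y622 value was 0.053 without a filter on low values and 0.0553 with the mean over genes. X-linked genes lay above N2 in 71.6% of cases in y607, 67.1% in y618 and 69.4% in y622, against 45.6%, 44.7% and 51.3% of autosomal genes. The X medians of all 3 exceeded the 10000 matched random lists. No autosome left the range -0.05 to 0.03 in y607 and in y618, or -0.02 to 0.02 in y622. Among genes with means over the 8 groups of 10 to 100 the shift was 0.11 in y607, 0.10 in y618 and 0.00 in y622, and from 100 to 500 it was 0.18, 0.16 and 0.13. Against N2-L4440 the 3 shifts were larger, 0.23, 0.21 and 0.20, because N2-L4440 itself had an X shift of -0.10 from N2. The 2 untreated groups thus differed by about as much as y622 or set-4(n4600) did from N2, in the other direction. Compared directly with y607, e428 had a further X shift of 0.35 (0.32 to 0.37), y618 one of -0.02 and y622 one of -0.05. The y alleles were thus close to one another and e428 stood well above them.

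The only gene that changed in y607 in the authors' deposited table was srw-85, from a mean of 343 to 12.9 (fold 0.0377, adjusted p 8.6e-17), and 19719 of 19722 genes had an adjusted p of 1. In y618 the authors' DESeq called 0 genes, and the authors' deposited table gave the lowest adjusted p, 0.0936, to the glucuronosyltransferase gene ugt-64 (fold 1.75). The authors' deposited table called 1 gene in y622, hrg-7, from a mean of 264 to 89.1 (fold 0.338, adjusted p 0.0102). That gene stood at 0.245 in e428 (7.38e-13) and, without passing the test, at 0.389 in y607 and 0.415 in y618 in the authors' deposited table, and at 0.552 in set-1(RNAi) (0.0461). Genes that did not pass had folds in the authors' deposited table of 1.64 for meg-2, 1.43 for meg-1, 1.39 for meg-4, 1.90 for the stress-protein gene lea-1 and 0.506 for the prion-like gene abu-11, all in y607. The meg genes named here are X-linked and were picked from the 5 largest X-linked rises in y607 with means of at least 500. In y618 the authors' deposited table had meg-2 at 1.54, lea-1 at 1.91 and abu-11 at 0.462, and in y622 lea-1 at 1.63 and the small heat shock gene hsp-16.41 at 1.83.

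The germline and early maternal list, whose transcripts are loaded into the egg, had medians of 0.40 log2 in y607, 0.39 in y618 and 0.16 in y622, above all random lists, and 21 of 21 genes lay above N2 in y607. That list held no X-linked gene. Examples in y607 were mex-1 (1.47), oma-1 (1.42) and pgl-3 (1.41) in the authors' deposited table, none past the test. Cell cycle genes had medians of 0.33, 0.28 and 0.16, with the replication genes mcm-2 (1.40) and pcn-1 (1.38) as y607 examples from the authors' deposited table. RNAi machinery genes had medians of 0.18, 0.25 and 0.20. Pharynx markers had medians of -0.28, -0.33 and -0.39, neuron markers -0.17, -0.12 and -0.13, body muscle markers -0.12, -0.14 and -0.28, and cuticle collagens -0.46, -0.44 and -0.51. These lists kept their direction against N2-L4440, with germline genes at 0.43, 0.35 and 0.13 and pharynx markers at -0.57, -0.58 and -0.70 less all genes. The embryos were of mixed stages per the labels, and the X shift of each allele stood beside these stage-related list values. Dosage compensation complex genes had medians of 0.11, 0.17 and 0.13, condensin and cohesin genes 0.13, 0.15 and 0.10, histone methylation genes 0.10, 0.15 and 0.07, and sex determination genes 0.12, 0.14 and 0.09, with no call in any. Apoptosis (0.13, 0.11, 0.06), heat shock (0.02, 0.08, -0.11), HOX (-0.03, 0.01, -0.06), pathogen response (-0.16, -0.06, -0.12), intestine (0.04, 0.05, -0.10) and epidermis (0.01, 0.03, -0.02) genes held no call either.

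Vitellogenin and other transcripts of the mother had high values in N2 itself. The adult carried-over list had medians of -3.62 log2 in y607, -3.70 in e428, -3.91 in y618, -3.56 in y622 and -4.39 in set-4(n4600), yet none of its genes passed the authors' test. For the yolk gene vit-2 the authors' deposited table gave a mean of 1323 in N2, with a fold of 0.00571 in y607 and 0.031 in e428 (adjusted p 0.911). N2-L4440 had a median less all genes of -2.38 from N2 on the same list. Pooled means cannot show whether an N2 sample held adult tissue, so values of adult genes against N2, and of single cuticle genes such as rol-8, are uncertain. The cuticle list as a whole had a median less all genes of -0.05 in N2-L4440 against N2, and of -0.54 in e428 and -0.43 in set-4(n4600) against N2-L4440.

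**Figure D2:**
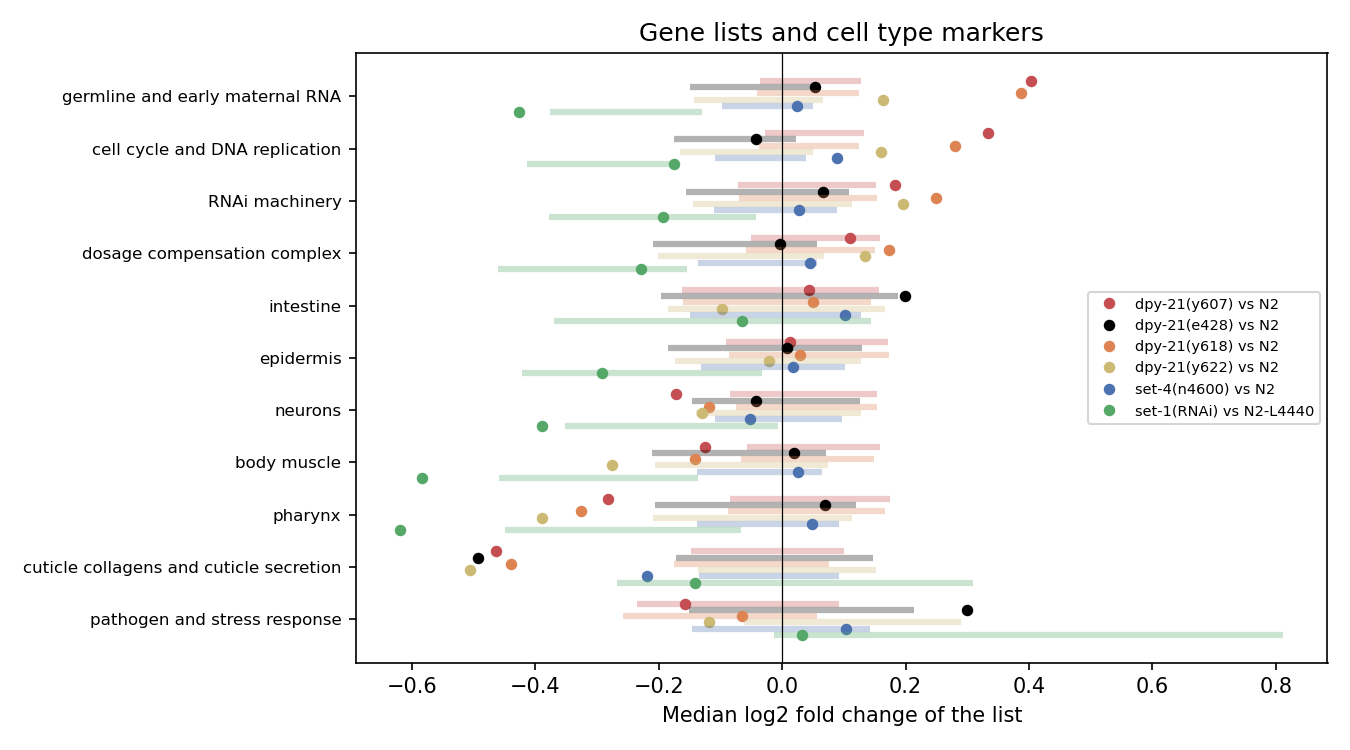
Median log2 ratio of 11 gene and marker lists in each comparison, with bars for the central 95% of matched random lists. Germline genes had medians of 0.40 in y607 and -0.43 in set-1(RNAi), and pharynx markers -0.28 and -0.62.

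The comparison of set-4(n4600) with N2 asked what loss of the H4K20me2 and H4K20me3 methyltransferase does to X repression. Few single genes changed, and X as a group lay above the autosomes about as far as in the y alleles. The calcium-sensor gene ncs-4, the G-protein-coupled receptor kinase gene grk-1 and its neighbour F19C6.2 rose from X, together with argn-1. On autosomes the citron-kinase-related gene citk-1 and lea-1 fell along with set-4.

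Changed genes in the authors' deposited table numbered 18, of which 9 were higher and 9 lower, and 4 of the higher genes were X-linked, ncs-4 (fold 5.99, adjusted p 5.46e-11), argn-1 (2.53, 0.00111), F19C6.2 (2.04, 1.16e-09) and grk-1 (1.61, 0.00172). grk-1 and F19C6.2 lie next to each other on X, so reads of one could have been counted for the other. ncs-4 lies close by, with starts at 9991197 for grk-1, 10000881 for F19C6.2 and 10177178 for ncs-4. These calls thus came from 1 stretch of X, and whether they share a local cause in that strain was not tested. Autosomal rises in the authors' deposited table were F56A4.3 (fold 22.5, adjusted p 0.00715, mean 1.37 to 30.8), C55C3.3 (5.93, 0.000725), sri-70 (3.69, 0.0345), B0511.11 (2.09) and the lectin gene clec-72 (1.78). Falls in the authors' deposited table were set-4, srw-85 (0.0422, 1.12e-20), ZK1025.3 (0.0907, 0.00217), B0205.13 (0.193, 0.00133), citk-1 (0.298, 3.74e-22), pgph-3 (0.413), F42A9.6 (0.451), lea-1 (0.554) and rips-1 (0.589). The direction of lea-1 was opposite in e428, where the authors' deposited table had it higher at 1.70 (adjusted p 0.000717).

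The X shift of set-4(n4600) was 0.10 log2 (0.09 to 0.11), equal to 1.07-fold, with 65.9% of X-linked and 45.7% of autosomal genes above N2. No autosome moved outside -0.01 to 0.01. The shift was 0.07, 0.13, 0.11 and 0.08 from the lowest to the highest expression class, and 0.20 against N2-L4440. Cell cycle genes had a median of 0.09 (percentile 99.9), condensin and cohesin genes 0.06 (98.9) and histone methylation genes 0.04 (98.2), the last with set-4 as the only call. Inside the random range lay the medians of germline (0.02), dosage compensation (0.05), sex determination (0.05), RNAi machinery (0.03), apoptosis (-0.03) and HOX (0.04) genes. Heat shock genes had a median of -0.20 (percentile 0.10) and cuticle collagens -0.22 (percentile 0.09), with no call in either. Pharynx (0.05), body muscle (0.03), neuron (-0.05), epidermis (0.02), intestine (0.10) and pathogen response (0.10) lists held no call.

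The comparison of set-1(RNAi) with N2-L4440 asked what loss of the H4K20me1 methyltransferase does, in embryos of which about 95% die per the labels. The X chromosome did not separate from the autosomes. Many muscle, pharynx, neuron and maternal markers fell, including the twitchin gene unc-22, and so did the chaperonin gene hsp-60 and the histone methyltransferase gene set-26. Rises included the acyl-CoA dehydrogenase gene acdh-1, the ferritin gene ftn-1 and the antimicrobial peptide gene nlp-29. The male-determining gene her-1 rose as well, together with the male differentiation genes mab-3 and dmd-3.

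By the authors' deposited table, 1364 genes were higher and 2868 lower. The authors' means summed to 25.2 M in set-1(RNAi) and 30.8 M in N2-L4440, so the count of falls depends on their scaling. Genes with control means of at least 1000 held 92.2% of the signal in N2-L4440 and 89.8% in set-1(RNAi). Calls at equal totals could not be made. X supplied 207 of the rises and 375 of the falls, so 7.49% of X-linked genes rose and 13.6% fell, against 6.81% and 14.7% of autosomal genes. The X median and the autosomal median were both -0.06 log2, a shift of 0.01 (-0.02 to 0.02), and 3613 of 10000 matched random lists lay below the X median. Set against set-4(n4600), each with its own control, the X shift differed by 0.10 (0.07 to 0.12). With N2-L4440 as control for both, the shifts were 0.20 in set-4(n4600) and 0.01 in set-1(RNAi), so the difference depended on the control. Across expression classes the set-1(RNAi) shift ran from -0.10 in the lowest to 0.05 in the highest.

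The largest rises in the authors' deposited table were C49G7.12 (fold 23.9, adjusted p 2.11e-14, mean 4.91 to 117), ZK177.9 (23.3, 1.89e-11), arf-1.1 (18.9, 2.56e-11) and acdh-1 (17.5, 4.74e-27). Further rises in the authors' deposited table were irg-2 (9.37), pals-5 (5.95), ftn-1 (5.68, 1.43e-06), sod-3 (4.22) and nlp-29 (3.33, 2.29e-21). X-linked rises in the authors' deposited table included the ABC transporter gene mrp-2 (2.65), fipr-21 (2.60), tatn-1 (1.92) and the potassium channel gene kqt-1 (1.70). The deepest falls in the authors' deposited table were Y48G8AL.12 (0.235, 7.74e-21), F55G11.2 (0.276, 0.000304), set-1 and dct-5 (0.315, 0.0331), followed by C02E7.7 (0.367) and ram-2 (0.371).

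Sex determination genes split. her-1 (3.59, adjusted p 4.24e-15), mab-3 (3.66) and dmd-3 (2.92) rose in the authors' deposited table, while fem-1, fem-2, fox-1 and sea-2 fell, and the list median was -0.07 log2. The authors' control means were 137 for her-1, 44.1 for mab-3 and 67.7 for dmd-3 in the authors' deposited table, and genes with control means of 10 to 100, the class of mab-3 and dmd-3, had a median fold of 1.63, with 80.1% above control and 780 called higher. In the class of her-1, 100 to 1000, the median fold was 0.959, with 43.2% above control, 377 called higher and 563 lower. Highly expressed genes lay low as a class, since genes with control means of at least 1000 had a median fold of 0.842 and included 2299 of the falls, so percentiles among random lists matched for expression stand beside the larger list medians. Dosage compensation complex genes had a median of -0.23 (percentile 84.4), and 5 of 10 fell in the authors' deposited table, dpy-21, dpy-27 (0.729), sdc-3 (0.76), dpy-26 (0.796) and sdc-2 (0.805). Histone methylation genes had a median of -0.29 (percentile 33.6) with 12 of 25 lower, led in the authors' deposited table by set-1 and set-26 (0.515, 4.14e-25). Condensin and cohesin genes had a median of -0.20 with 4 of 14 lower, kle-2, scc-3, coh-1 and pqn-85. Body muscle markers had a median of -0.58 (percentile 0.05) with 8 of 10 lower, pharynx markers -0.62 (0.03) with 8 of 8 lower, neuron markers -0.39 (0.96) with 8 of 13 lower, and germline and early maternal genes -0.43 (0.34) with 12 of 21 lower. These 4 lists lay below the central range of lists of equal expression, while the dosage compensation and histone methylation lists lay within it. As examples the authors' deposited table gave unc-22 a fold of 0.564 and the troponin T gene tnt-4 one of 0.527. Epidermis markers had a median of -0.29 with 4 of 9 lower, lin-26, nhr-25, dpy-7 and ajm-1, and intestine markers -0.07 with 4 of 11 lower, ifb-2, act-5, pho-1 and the protease gene asp-1. Cuticle collagens had a median of -0.14, with dpy-8 and sqt-1 (2.51 in the authors' deposited table) higher and 8 lower. The pathogen and stress list had a median of 0.03 (percentile 4.89), with 7 higher and 3 lower, the last being ugt-63, dod-17 and hsf-1. Heat shock genes had a median of -0.11 and 4 fell, hsp-1, hsp-6, hsp-90 and hsp-60 (0.538, adjusted p 3.52e-20 in the authors' deposited table). Apoptosis genes had a median of -0.16, with the death activator gene egl-1 higher (1.77, adjusted p 0.0376) and the caspase gene ced-3 lower (0.739) in the authors' deposited table. RNAi machinery genes had a median of -0.19, with rde-1 (0.787) and ergo-1 (0.73) lower in the authors' deposited table. Cell cycle genes had a median of -0.17 (percentile 98.1) and HOX genes one of -0.20, with no call in either list. The sperm list had a median of 1.34 on 3 genes (percentile 94.4), with the major sperm protein gene msp-45 higher (5.67, adjusted p 0.0138) in the authors' deposited table, and the adult carried-over list one of 0.54 (percentile 70.2). In the other groups the sperm list had medians of -0.19 in y607, 0.02 in e428, -0.25 in y618, 0.00 in y622 and 0.13 in set-4(n4600).

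Hi-C maps of N2 and y607 embryos on ce11 asked whether the X chromosome loses its domain boundaries when the demethylase gene is mutated. The 8 strongest N2 boundaries of X all stayed insulation minima in y607, at the same or a neighbouring bin, and each autosome kept 7 or 8. Of the 8 on X, 4 were weaker in y607 and the others stronger, with the largest gain at 5000001 and the largest loss at 6300001. Contacts within X moved toward short distances by more than on any autosome.

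Mean boundary strength on X, in log2 insulation units at 50 kb, was 0.267 in N2 and 0.277 in y607, a change of 0.01 with a standard deviation of 0.0684 over 8 boundaries. On autosomes the mean change was 0.00 and the single chromosomes ran from -0.02 to 0.03. Of the autosomal boundaries 17 lay within 500 kb of an empty bin, against 0 on X. With insulation recomputed and empty bins left out, the autosomes ran from -0.01 to 0.03. Chromosome IV then went from -0.02 to 0.02, and X stayed inside the range at 0.01. Stronger X boundaries in y607 began at 2000001 (0.365 to 0.447), 4050001 (0.292 to 0.314), 5000001 (0.186 to 0.305) and 11750001 (0.359 to 0.408). Weaker ones, 4 in number, began at 3000001 (0.324 to 0.273), 6300001 (0.207 to 0.150), 11050001 (0.216 to 0.166) and 14500001 (0.191 to 0.154). Insulation itself moved toward 0 at 3000001 (-0.26 to -0.18), 4050001 (-0.30 to -0.27), 6300001 (-0.30 to -0.12), 11050001 (-0.31 to -0.15), 11750001 (-0.41 to -0.38) and 14500001 (-0.30 to -0.18), and away from 0 at 2000001 (-0.11 to -0.23) and 5000001 (-0.28 to -0.33). The spread of the whole insulation profile narrowed on X from 0.191 to 0.177 and on autosomes from a mean of 0.247 to 0.212, and the 2 X profiles had a correlation of 0.953.

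**Figure D3:**
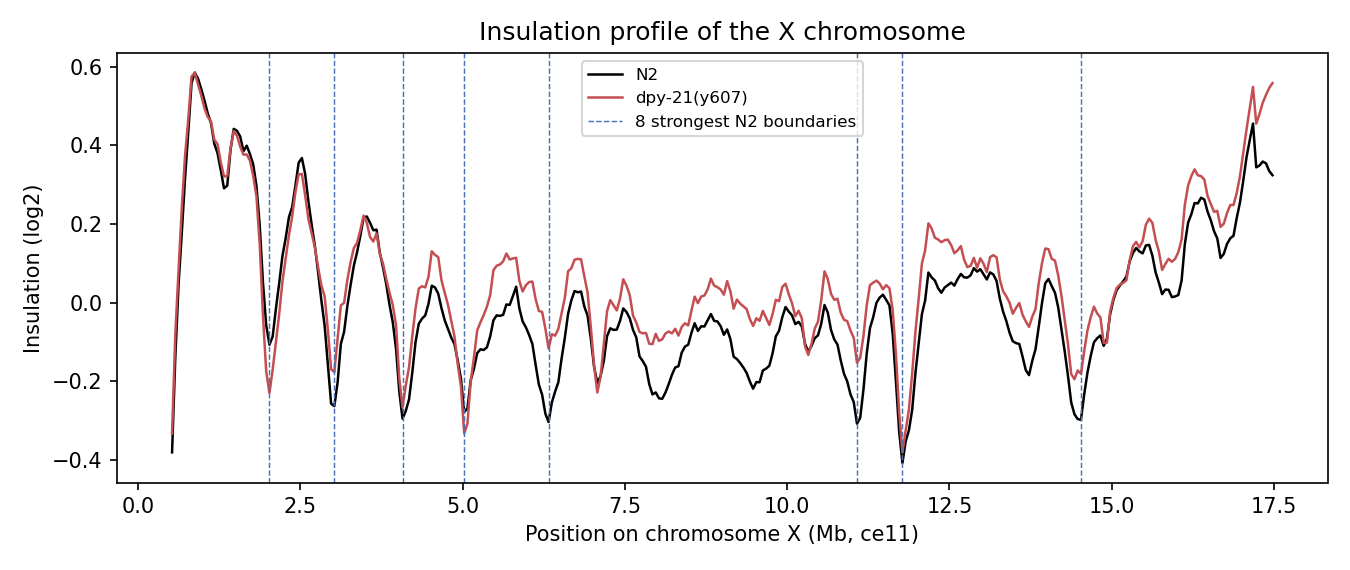
Log2 insulation along X in N2 (black) and y607 (red), with dashed lines at the 8 strongest N2 boundaries. Insulation at 6300001 went from -0.30 to -0.12.

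Contacts of X at 0.1 to 0.5 Mb took a share of the contacts within X 1.32 times as large in y607 as in N2, against 1.22 to 1.28 on the autosomes. At 0.5 to 1 Mb the X ratio of 1.06 lay inside the autosomal range of 0.998 to 1.07. At longer distances X fell below every autosome, with 0.982 at 1 to 2 Mb (autosomes 0.988 to 1.05), 0.891 at 2 to 5 Mb (0.927 to 0.955) and 0.640 at 5 to 10 Mb (0.661 to 0.688). Contacts within the same chromosome made up 59.6% of X contacts in N2 and 74.3% in y607, and a mean of 59.4% and 73.5% on autosomes. All chromosomes thus shared most of the move toward short and same-chromosome contacts, and X went somewhat further. Each genotype came as 1 averaged map, so an effect of genotype cannot be told apart from a difference between the libraries behind the maps. This holds for the move shared by all chromosomes, and the cause of the X excess was not tested.

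**Figure D4:**
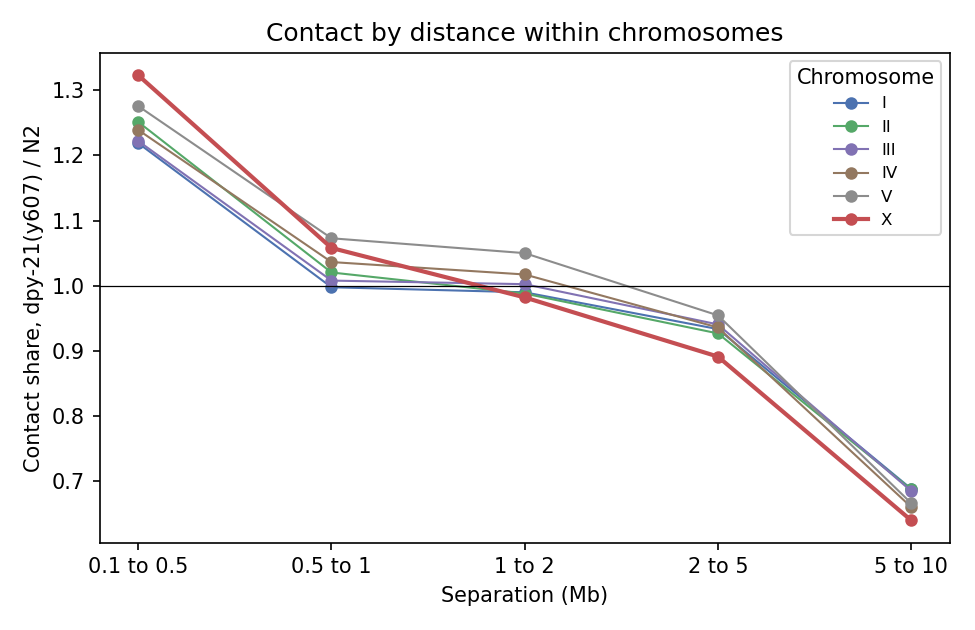
Share of same-chromosome contacts in y607 divided by that in N2 in 5 distance windows, for each chromosome. X had the highest ratio at 0.1 to 0.5 Mb (1.32) and the lowest at 5 to 10 Mb (0.640).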

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

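After the results were seen, thresholds of 0.01 and 0.1 and a minimum mean of 10 were added for the calls. For X shifts a minimum mean of 500, no pseudocount and N2-L4440 as control were added then. For Hi-C boundaries the z-score, chromosome-end, empty-bin and share-of-strength settings were also added then. Of 101 alternatives for 17 results, 62 planned and 39 added, 82 gave the same reading, 14 moved a value by more than the standard deviation over the 5 autosomes, 3 lowered a count and 2 raised one beyond 1.5 times, and 0 reversed the direction of a value outside the autosomal range. Of the 53 for X shifts 42 stayed within that standard deviation, though not always within the bootstrap interval. Values near 0 changed sign, the set-1(RNAi) shift to -0.0354 with no filter, -0.00664 with the mean over genes and -0.00346 when matched on expression, and the X difference in boundary strength to -0.00222 with a 1 Mb window. At an adjusted p under 0.01 the counts of changed genes were 959 in e428, 2584 in set-1(RNAi) and 0 by the authors' DESeq in y622, and under 0.1 they were 1 in y618, ugt-64, and 3 in y622, hrg-7, cnc-3 and col-111, as the moved threshold requires. Against N2-L4440 the X shift was 0.23 in y607, 0.54 in e428, 0.21 in y618, 0.20 in y622 and 0.20 in set-4(n4600). In e428 it was 0.39 with no filter, 0.45 with a mean of at least 50 and 0.39 with a pseudocount of 10, and in y622 it was 0.053 with no filter, 0.11 with a mean of at least 50 and 0.0553 with the mean over genes. For these the cause was not tested. The X difference in boundary strength, 0.01, became 0.112 on the z-score and 0.0262 as a share of N2 strength, both on other scales and both inside the autosomal range. Taking the spread of the insulation profile (-0.01 on X, -0.05 to -0.02 on autosomes) or y607 boundaries (0.05 on X, 0.02 to 0.05 on autosomes) put X just outside that range. The X excess of contacts at 0.1 to 0.5 Mb, 0.0816, was 0.111 with the genome-wide total, and the cause was not tested. Other tests on libraries, fits on the groups of 1 comparison, refitted normalizations, replicate blocks, pseudocounts for the calls and leaving out single libraries were planned and not run, since they need values per library. No paired analysis was possible because each group had 1 pooled value. What depth and the number of libraries limit in the calls was not tested, since neither is known per library, and an adjusted p of 1 covered 19719 of 19722 genes in y607 but 3415 of 19913 in y622.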

Other observations

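The tests on the chromosome V stretch and on the mix of embryo stages, and the split of X-linked genes by their e428 call, were chosen only after the results were seen. The X-linked genes that rose in e428 lay above the other X-linked genes in set-4(n4600), y607 and y618, hardly so in y622 against N2, and below them in set-1(RNAi). Less the autosomes, 949 of them had a median of 0.19 log2 in set-4(n4600) against 0.03 for the other 1382 X-linked genes, and 0.33 against 0.11 with N2-L4440 as control. The same genes had medians of 0.19 in y607 and 0.17 in y618 against 0.11 and 0.08, and with N2-L4440 0.31 and 0.30 against 0.16 and 0.15. In y622 they had 0.10 against 0.08, and 0.26 against 0.13 with N2-L4440. In set-1(RNAi) the order was turned, with -0.13 for the e428-called genes and 0.15 for the rest. The e428-called genes were called against N2, so a low value in N2 alone would raise them in every comparison with N2. The values with N2-L4440 do not share that control. The e428-called genes were not matched to the others in expression. In set-1(RNAi) the median log2 ratio was 0.69 at control means of 10 to 100 and -0.25 at 1000 or more. The turned order there cannot be told apart from expression level.

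Several genes moved in more than 1 comparison. C42D4.3 rose in e428 (4.57) and in set-1(RNAi) (2.80) in the authors' deposited table, and Y48G8AL.12 fell in both (0.132 and 0.235). F56A4.3 rose in e428 (8.88) and set-4(n4600) (22.5) in the authors' deposited table. The authors' deposited table had srw-85 near 0 in e428 (0.0036), y607 (0.0377) and set-4(n4600) (0.0422), with 0.956 in y618 and 1.14 in y622 against N2, and 1.33 in set-1(RNAi) against N2-L4440. In the authors' deposited table the X-linked gene tatn-1 fell in e428 (0.474) and rose in set-1(RNAi) (1.92).

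The X shift in y607, y618, y622 and set-4(n4600) had technical explanations, of which the values argue against a difference in expression level between X-linked and autosomal genes. A low X level in the shared N2 control would leave no shift against N2-L4440, where the median of the 4 shifts was 0.208 (0.198 to 0.231), though food also differed there. N2-L4440 itself had an X shift of -0.10 from N2, so these larger shifts followed from that difference. They cannot tell whether the X level of either untreated group was typical. With autosomal genes matched on expression the median shift was 101% of the unmatched value. A changed mix of embryo stages stays open for set-4(n4600), whose shift of 0.101 came with a germline median 0.0319 from all genes but with cell cycle genes at percentile 99.9 and cuticle genes at 0.09. It stays open for the y alleles too, since set-4(n4600) differed from y607 by -0.0123 (-0.0280 to 0.00551), between the bounds set, and effects of these mutations and of embryo age cannot be told apart without staged embryos.

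Genes of low expression had higher values after set-1(RNAi). Among 3893 genes with a mean under 10 in N2-L4440, the median fold was 2.49 and 88.1% lay above control, and their share of all signal went from 0.0507% to 0.172%. Loss of X repression was argued against, because X-linked genes differed from autosomal ones by -0.0472 among them. Carried-over genomic DNA, which grows with gene span, and broad loss of silencing cannot be told apart, since the added signal had a rank correlation of 0.155 with span, between the bounds of 0.1 and 0.3. In y622 genes under 10 in N2 had a median fold of 1.77, against 1.01 in y607.

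The near absence of neighbouring genes in e428 covered 6 listed genes within 24.1 kb of chromosome V, from 19421442 to 19445539 on a build not given in the sources used here. The fold of C25F9.16, the 1 gene of the stretch that the naming rule had not picked, was 0.0626 in the authors' deposited table, which a missing piece of chromosome in that strain predicts, though from a low mean of 5.47. Loss of dpy-21 function in every allele was argued against for the stretch as a whole by a median fold of 0.995 over its 5 named genes in the other 3 alleles. For srw-85 alone the alleles were split in the authors' deposited table, near 0 in y607 (0.0377) but 0.956 in y618 and 1.14 in y622. It was also near 0 in set-4(n4600) (0.0422), which is not a dpy-21 allele. The left edge is not fixed, since the next gene, C25F9.9, had a fold of 0.192 from a mean of 3.91 in the authors' deposited table, while C25F9.5 (1.45) and C25F9.4 (2.13) beyond it and M04C3.2 (0.753) and Y43F8B.14 (2.61) to the right were not near 0. A deletion carried by the e428 strain remains a hypothesis from expression alone, and an effect of e428 itself was not tested.

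A hypothesis set before the result was seen held that X-linked genes change more in y607 where insulation changes more. Across 340 bins with 2269 genes, the rank correlation between the absolute insulation change and the median expression change was 0.138, with a circular-shift p of 0.0451 from 355 shifts. That is 1 weak test on pooled values, and it gives no direction of cause. X also lay 0.073 above the line of short-range contact ratio on chromosome length drawn through the autosomes, against 0.0186 for the farthest autosome. The line was fitted to the autosomes with X left out, which keeps the autosomes close to it, so these distances are not directly comparable.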
